A study of Drosophila melanogaster with 4 samples.

How the data were processed

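RNA polymerase II was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Kc167, a Drosophila melanogaster line derived from embryos and labelled female. The antibody, ab5408, is directed against the repeated heptapeptide of the carboxy-terminal domain of the polymerase's largest subunit. Per the labels' protocols, cultures were fixed in 1.8% formaldehyde for 10 min, chromatin was sheared by sonication, and the antibody was incubated with it for 15 hours. The 4 samples are 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group. The input libraries have no region list of their own and were not analysed here. Nothing in the labels says whether the replicates came from separate cultures, so agreement between them may measure technical spread alone. No read counts were at hand, so whether both ChIP libraries differ by more than sampling noise could not be tested.

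Per the submitters' processing notes, Bowtie 0.12.7 was among the tools used. The caller of the regions, its threshold and the control used are not given in the sources used here. Per the file headers, coordinates refer to FlyBase release 5. The authors deposited 3 lists of regions: 1 for each ChIP replicate and 1 for the whole series, called the series list below. Each region is typed by the authors as enriched or depleted and carries 1 score deposited by the authors, which is above 0 in every enriched region and below 0 in every depleted one. The scale of the score is not stated, and it was read from the values. Some scores occur exactly in several regions. Between such values in the series list, 16 of 2926 pairs differed by the log2 of a whole number from 3 to 10 that is not a power of 2 (tolerance 1e-06), with 7 of 4095 pairs in replicate 1 and 4 of 2346 in replicate 2. The same search found 0 pairs on the natural-log scale and 0 on the log10 scale in each list, powers of 10 left out. Scores are therefore given on a log2 scale, and which quantities form the ratio is not known. Because the lists hold no counts, the depth of the libraries is unknown, and no interval that needs it is given.

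Enriched regions were compared as deposited. A region was shared when it overlapped a region of the other list by at least 1 bp (bedtools 2.31.1 gave the same count as the Python code). Chance overlap was obtained by shifting 1 list circularly along each chromosome arm, with 100000 draws from all possible shifts and a one-sided permutation p, of which 1e-05 is the smallest possible. Differences of medians and correlations across regions were tested by two-sided permutation with 100000 or 10000 resamples. Regions are not independent replicates, so these p-values describe the 2 lists, not a population of cultures. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. They treat each region as an independent draw, and regions were unevenly spaced, so the intervals may be too narrow. Means are given ± SD over the 2 replicates. The 5 major arms are 2L, 2R, 3L, 3R and X. Lengths of arms came from the file headers. Code was run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated lists of 4997 regions: of 4522 regions simulated as shared it recovered 4522, and 0 of 20 independent lists gave p under 0.05. Simulated regions were placed at random along each arm, and shared ones kept nearly all of their sequence, so this checked the code alone. The error rate of the shift test in unevenly spaced lists was not checked.

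Before the data were examined, 24 gene lists, a window of 250 bp on either side of transcription starts and tests of regions at starts and within the lists had been set. These were not run, because the gene table at hand is of release 6, whose coordinates were not mixed with those of release 5. Regions are therefore identified by position, and no gene is assigned to them. The regions named in the text follow the rule set beforehand: the 10 regions with the best mean rank of score over both replicates, the 5 widest of the series list, and the 5 highest-scoring unshared regions of each replicate, ties kept. The values along the arms, the density of 2R, the scores on the X and the Fisher's exact tests were added after the data were seen. The settings varied were the threshold (regions at or above the median score of each list), overlap of at least 50% of both regions, merging of regions under 500 bp apart, the major arms alone, random placement, each replicate alone, width in place of score, all overlapping pairs, and sharing defined by the series list.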

Results

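The data comprised 3 lists of regions bound by RNA polymerase II in Kc167 cells, an embryo-derived Drosophila line. ChIP replicate 1 held 4997 enriched regions, ChIP replicate 2 held 4967, and the list of the whole series held 5288. The lists also held 17, 21 and 91 regions typed as depleted. Enriched regions covered 19.4 ± 0.2 Mb (SD, n = 2) per replicate. On the 5 major arms, which together measure 119 Mb, they covered 15.8 ± 0.16% of the sequence (SD, n = 2). The median region was 2675 bp wide in replicate 1 and 2686 bp in replicate 2, and its score on the log2 scale was 1.38 in both. Broad regions of more than 10 kb made up 4.99 ± 0.38% of the regions (SD, n = 2) and 18.3 ± 1.0% of the covered length. Wider regions had higher scores, with a Spearman correlation across regions of 0.58 in replicate 1 and 0.57 in replicate 2; regions are not independent replicates.

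The first comparison asked how far the polymerase map of one library was recovered in the other. Polymerase regions lay at the same places in both replicates. Of the regions of replicate 1, 4825 were found in replicate 2 (96.6%, 95% interval 96.0 to 97.0), and 4762 of those of replicate 2 were found in replicate 1 (95.9%, 95% interval 95.3 to 96.4). Shifted copies of the other list gave 26.5% on average in either direction, and none of the 100000 draws exceeded 2123 regions (one-sided permutation p = 1e-05, the smallest they can give). The replicates shared 18.6 Mb, which is 91.7% of the sequence covered by either. Matched edges were close: the median distance between starts was 28 bp and that between ends 27 bp, over the 4384 regions that paired 1 to 1.

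The deposited scores were also similar in the replicates. How they were scaled is not known, so they do not compare the level of enrichment between the libraries. Across the 1-to-1 regions the scores had a Pearson r of 0.99 and a Spearman rho of 0.99 (two-sided permutation p = 1e-05 for both, the smallest possible). Over all 4950 overlapping pairs the Spearman rho of the scores was lower, at 0.94, and that of the widths of the 1-to-1 regions was 0.97. Replicate 2 scored higher than replicate 1 by 0.02 on average, with an SD of the difference of 0.13. In 95.8% of these regions the scores lay within 0.25 of each other.

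**Figure D1:**
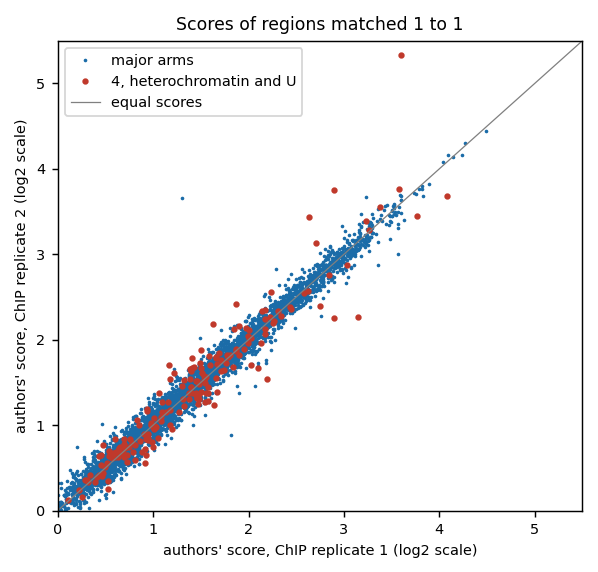
Score of each of the 4384 regions matched 1 to 1, replicate 1 on the x axis and replicate 2 on the y axis, both on the log2 scale, with the line of equal scores. The points lie along the line (Spearman rho 0.99); a region on scaffold U stands apart with 3.60 in replicate 1 and 5.34 in replicate 2.

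The strongest regions lay on several arms, and among the 10 ranked highest the widths in replicate 1 ran from 2086 to 4837 bp. The best mean rank belonged to 2R from 13029764 to 13034600 in replicate 1, with a score of 4.46 ± 0.03 (SD, n = 2), followed by 2L from 21213762 to 21216295 with 4.29 ± 0.02. Another pair on 2L lay close together, at 13214718 to 13217392 (4.20 ± 0.05) and at 13243238 to 13246057 (4.13 ± 0.05). On 3R, the region from 19683905 to 19686483 scored 4.14 ± 0.0032 and the one from 3918749 to 3921020 scored 3.81 ± 0.01. On 3L, the regions from 3089699 to 3092298 and from 1462494 to 1465148 scored 4.05 ± 0.03 and 3.86 ± 0.05. The X chromosome contributed the region from 10241061 to 10243562, with 3.79 ± 0.04. Among the 10, the region on U, a scaffold of unplaced sequence, from 2929343 to 2931428 was the one whose scores differed most between replicates (4.47 ± 1.23, SD, n = 2).

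The 5 widest regions of the series list, called domains here, were covered over most of their length by regions of each replicate. The series list was made from the same samples, so this coverage is no independent evidence of recovery. The widest region of the series list spanned 39.2 kb of 3R from 1095847 to 1135080, and a single region of each replicate covered 99.8% of it. A second domain on 3R, from 7414159 to 7450329, was 36.2 kb wide, and a single region covered 98.6% of it in replicate 1 and 99.5% in replicate 2. The domain on 2R from 4013627 to 4045163 (31.5 kb) was split into 2 regions in each replicate, which covered 99.2% and 99.9% of it. The domain on the X from 8772494 to 8802289 (29.8 kb) was split into 3 regions in replicate 1, covering 89.1%, and 5 in replicate 2, covering 95.3%. The domain on 2R from 14012027 to 14040357 (28.3 kb) was split into 3 in each, covering 85.3% and 93.3%. The scores of these 5 domains in the series list lay between 1.48 and 2.09. Over all enriched regions of that list the median score was 1.27 and the upper quartile 1.91.

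Regions found in one replicate alone were weaker and narrower. In replicate 1, the 172 unshared regions had a median score of 0.39 against 1.41 for shared ones, and a median width of 1530 bp against 2746 bp. In replicate 2, the 205 unshared regions had a median score of 0.44 against 1.43, and a median width of 1527 bp against 2776 bp. Each of the 4 differences had a two-sided permutation p of 1e-05, the smallest possible, and the same value after Benjamini-Hochberg adjustment over the 4 tests. With the regions divided by score into 10 bins of equal size, 80.2% of the lowest bin of replicate 1 and 79.5% of that of replicate 2 were shared, and from the third bin upward the share lay between 97.0% and 99.8%.

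**Figure D2:**
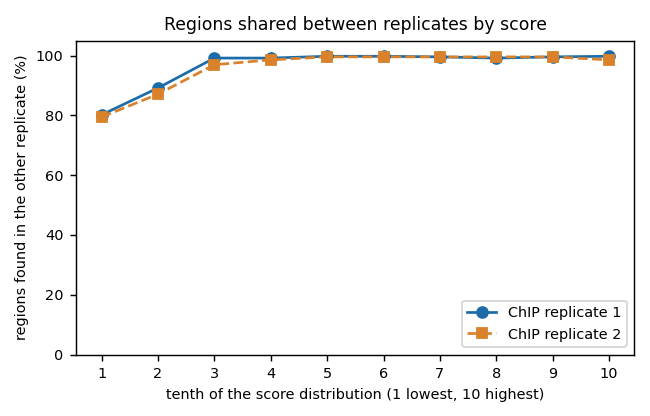
Percent of enriched regions that overlap a region of the other replicate (y axis), in 10 bins of equal size from the lowest to the highest scores (x axis), for each ChIP replicate. The share rises from 80.2% and 79.5% in the lowest bin to 99.8% and 98.6% in the highest.

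A few unshared regions had high scores. The highest in replicate 1 lay near the end of 2L, from 23008450 to 23010235, with a score of 3.66. The others were on U from 8055152 to 8057160 (2.50) and on 2L from 21424016 to 21426217 (2.38), from 21453405 to 21455037 (2.16) and from 22796090 to 22797749 (2.16). In replicate 2 they were on U from 6762391 to 6764427 (3.51), from 8397916 to 8399462 (3.29), from 8318404 to 8319706 (2.86) and from 9819556 to 9821213 (2.70), on 3R from 17129593 to 17131089 (2.87) and on 2L from 21429922 to 21431265 (2.70). All of them overlapped an enriched region of the series list. Unshared regions made up 9.52% of the regions off the major arms against 3.86% on them in replicate 2 (Fisher's exact test, p = 2.2e-04). In replicate 1 the shares were 5.88% and 3.33%, a difference that did not pass 0.05 (Fisher's exact test, p = 0.0557).

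The next comparison was between each replicate and the series list, which was made from the same samples and is no independent evidence. The series list contained 99.2% of the enriched regions of each replicate, and the replicates contained 87.3 ± 0.37% of its regions (SD, n = 2). Both replicates had a region at 4478 of its 5288 regions, 1 replicate at 280, and neither at 530. The 530 had a median score of 0.36 and a median width of 1236 bp, against 1.40 and 3111 bp for those in both. The narrowest enriched region measured 1301 bp in each replicate and 1001 bp in the series list. Absence of such narrow regions from the replicate lists therefore does not show that the signal was missing there. The low scores were those of the 426 on the major arms (median 0.34); the 104 off them had a median of 1.12, against 1.27 for all series regions off the major arms, and 54 of the 530 scored above 2. Of the series regions off the major arms, 31.2% were in neither replicate, against 8.60% on the major arms (Fisher's exact test, odds ratio 4.83, p = 4.8e-29).

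The last comparison concerned chromosomes. The density of polymerase regions on the X differed from that on the 4 large autosome arms together by less than counting error. The X carried 39.5 ± 0.09 regions per Mb and the 4 large autosome arms together 40.1 ± 0.27 (SD, n = 2). Taken singly, 2R lay above the X (47.9), and 2L (37.3), 3L (39.0) and 3R (37.3) lay below it. The side of the pooled difference thus turned on 2R. The ratio of X to autosome density was 0.98 in replicate 1 (exact 95% interval 0.91 to 1.06) and 0.99 in replicate 2 (0.92 to 1.06). Median scores on the X and on the autosome arms were 1.42 and 1.36 in replicate 1 (two-sided permutation p = 0.164) and 1.40 and 1.39 in replicate 2 (p = 0.762). With 1 cell line, labelled female, there was no group of cells with another number of X chromosomes to compare with.

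Arm 2R was the densest. It carried 47.9 ± 0.03 regions per Mb, against 37.3 ± 0.55 on 2L, 39.0 ± 0.23 on 3L and 37.3 ± 0.30 on 3R (SD, n = 2). It held 26.0% of the autosomal regions of replicate 1 (exact 95% interval 24.6 to 27.4) and 26.3% of those of replicate 2 (24.9 to 27.7), with 21.9% of the autosomal length. These intervals treat regions as independent, so the excess on 2R may be less firm than they show. Chromosome 4, a small chromosome rich in heterochromatin, carried 41.4 ± 1.0 regions per Mb, within the range of the large arms, with a median score of 1.29 ± 0.03.

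Heterochromatin and unplaced sequence held fewer regions per Mb of full scaffold length. How much of that length reads could be placed on is not known, so the densities do not measure how much polymerase was there. The 6 heterochromatin scaffolds together carried 12.01 ± 0.08 regions per Mb and were covered over 3.72 ± 0.0018% of their length (SD, n = 2). Among them, 3LHet carried 23.5 regions per Mb in each replicate and 3RHet 3.77 ± 0.28, while XHet carried 34.3 ± 6.9 on a scaffold of only 0.204 Mb. Scaffold U carried 5.82 ± 0.63 regions per Mb, with a median score of 1.70 ± 0.04 against 1.38 ± 0.0079 on the major arms. On U, 18.5% of the scores in replicate 1 and 17.5% in replicate 2 repeated that of another region exactly. On the major arms these shares were 3.71% and 3.06%. None of the lists had a region on Uextra, and whether that scaffold was searched is not known.

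**Figure D3:**
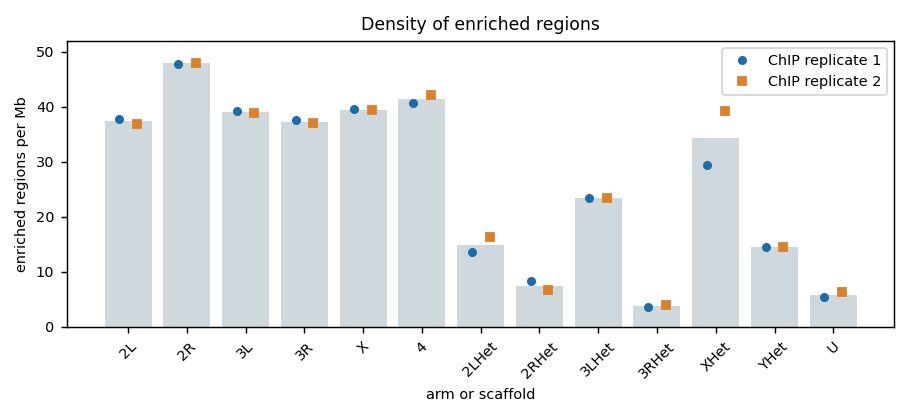
Enriched regions per Mb of full length (y axis) on each arm or scaffold (x axis). Bars are the mean of the 2 ChIP replicates and points are the replicates. Arm 2R stands above the other large arms at 47.9 per Mb, and the bars of the heterochromatin scaffolds lie below those of all large arms, though replicate 2 reaches 39.2 per Mb on XHet.

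Along the arms, polymerase coverage varied over short distances and in parallel in both replicates. Over 117 whole bins of 1 Mb the median coverage was 15.8% of the sequence. The lowest was on 2L from 14000001 to 15000000, with 3.11 ± 0.02% (SD, n = 2), followed by 2L from 17000001 to 18000000 with 4.26 ± 0.19% and 3L from 10000001 to 11000000 with 5.44 ± 0.34%. The highest was on 3R from 19000001 to 20000000, with 29.8 ± 0.39%, followed by 3R from 5000001 to 6000000 with 27.4 ± 0.02% and 2R from 3000001 to 4000000 with 26.9 ± 0.44%. The 2 Mb nearest the centromere differed between arms. On the X they carried 22.8 ± 0.35 regions per Mb against 40.7 ± 0.27 on the arm outside both ends, and on 3L 24.3 ± 1.1 against 39.7 ± 0.38. On 2R they carried 38.8 ± 1.8 against 47.5 ± 0.25. On 3R and 2L the direction was opposite, with 47.0 ± 0.71 against 37.2 ± 0.38 and 41.8 ± 1.8 against 36.2 ± 0.33. At the 2L end, 14 of the 86 regions of replicate 1 and 12 of the 81 of replicate 2 lay at 21.4 to 21.56 Mb. That stretch holds a row of evenly spaced regions described below, and the density without it was not computed. The SDs do not cover counting error.

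**Figure D4:**
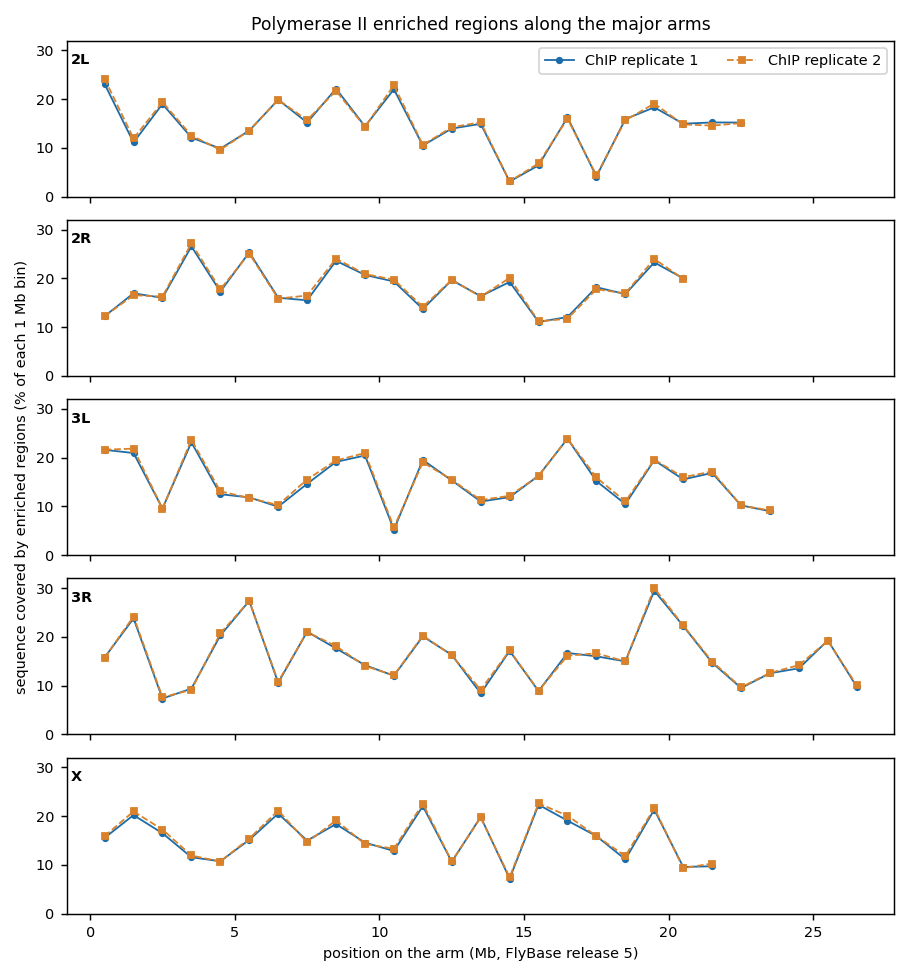
Percent of each 1 Mb bin covered by enriched regions (y axis) against position in Mb of FlyBase release 5 (x axis), a panel per major arm, with a line for each ChIP replicate. The lines of both replicates run together, from 3.11% on 2L to 29.8% on 3R.

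**Figure D5:**
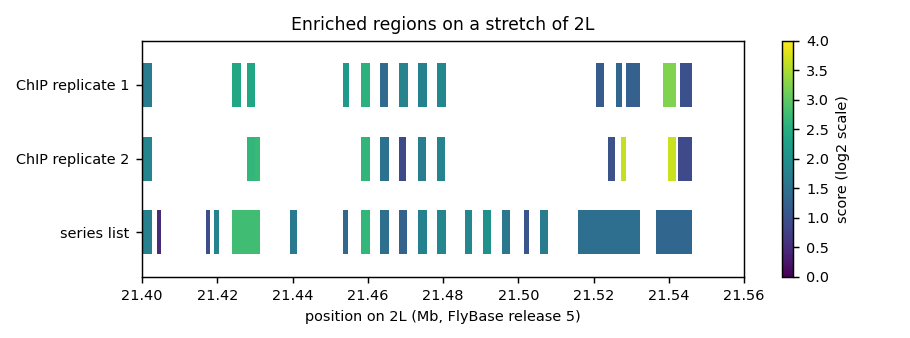
Enriched regions of the 3 lists between 21.4 and 21.56 Mb of 2L (x axis, FlyBase release 5), coloured by score on the log2 scale. The stretch holds 4 unshared regions of replicate 1 and 2 of replicate 2, and the series list has 19 regions there against 14 and 12 in the replicates.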

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

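All tests in this part were chosen after the result was seen. The authors' regions typed as depleted lie outside the comparisons of enriched regions, and are given here because those comparisons do not use them. Their number was 17 in replicate 1, 21 in replicate 2 and 91 in the series list. All 91 lay on the major arms, and their scores, down to -0.27, were close to 0 beside enriched scores of up to 4.77.

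The type given to these places differed between lists. Of the 91, 38 (41.8%) overlapped an enriched region of replicate 1 and 35 (38.5%) one of replicate 2, 54 in either and 19 in both, while 24 were depleted in either replicate, 9 of them in both, and 21 met no region of either replicate. Of the depleted regions of the replicates, 17 of 17 in replicate 1 and 16 of 21 in replicate 2 were depleted in the series list too. The overlap with enriched regions was above that of shifted copies (21.8% and 22.0%, one-sided permutation p = 1.0e-04, the smallest possible with 10000 shifts, and p = 6.0e-04), but the series list held 5014 of 5014 regions of replicate 1 and 4984 of 4988 of replicate 2 in either type, so the excess does not bear on whether the polymerase signal was below background there. The overlapping replicate regions scored at most 0.28, and 100% of them lay in the lowest 5% of their list, but a low score follows in part from choosing places by a negative series score; the median series-minus-replicate difference there was -0.16 in replicate 1 against -0.04 in other weak regions, and -0.16 in replicate 2 against -0.06. Of these differences, 20 of 38 and 16 of 35 lay below the 5th percentile of the other weak regions. A score near 0 whose sign differs between lists and a signal below background cannot be told apart here, because the lists share their samples and the places were chosen by sign, and no biological explanation was tested.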

How the results depend on the processing

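The 18 tested alternatives all kept their direction and stayed past 0.05. Sharing of replicate 1 regions ranged from 92.1% (50% of both regions shared) to 96.9% (merging), and that of replicate 2 regions from 92.7% to 96.5%, always above chance. The Spearman rho of the scores (0.99) was 0.94 over all overlapping pairs, and that of widths was 0.97. For values with no test, movements were judged against the small SD between the replicates. The share of series regions found in the replicates (87.3%) was 89.6% for regions at or above the median score, 88.7% after merging, 88.9% on the major arms, 85.4% with 50% of both regions shared and 86.9% with depleted regions counted too. The share of replicate regions found in the series list (99.2%) was 97.6% for regions at or above the median score, 99.2% on the major arms, 90.6% with 50% of both regions shared and 99.96% with depleted regions counted too. The X-to-autosome ratio (0.99) was 1.01 ± 0.0221 (SD, n = 2) for regions at or above the median score, a spread wider than its distance from 1, so a change of side is not shown; it was 0.97 after merging and 0.97 for covered sequence, and the cause of these movements was not tested. Each replicate alone gave 87.1% to 87.6%, 99.21% to 99.24%, and 0.98 to 0.99. Counting depleted regions and covered sequence were chosen after seeing the data. Planned tests at transcription starts and in gene lists were not run, for want of an annotation of release 5. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no values here. Depth is unknown, so whether the weak unshared regions reflect it could not be examined.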

Other observations

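All tests in this part were chosen after the result was seen. Polymerase regions were spaced less evenly than under random placement, leaving long stretches of the major arms without any. In both replicates together, 219 stretches of more than 100 kb had no enriched region, against 41.6 on average and at most 64 when the regions were placed at random (one-sided permutation p = 0.001, the smallest that 1000 placements can give). These stretches made up 29.5% of the major arms. The longest, 405 kb, lay on 3R from 2486760 to 2891707, beyond the longest of 383 kb in any random placement (permutation p = 0.001). It was followed by X from 11965505 to 12355941 (390 kb), 2L from 15772100 to 16141084 (369 kb) and X from 20530822 to 20898028 (367 kb). The series list had 2, 4, 1 and 2 regions in these stretches. Random placement took no account of where genes lie or of how much sequence reads were placeable on, and neither was measured here. Both tests therefore show uneven spacing alone, and its cause was not tested.

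In the series list, 54 regions with scores above 2 were in neither replicate. The highest were on U from 2925767 to 2927771 (4.77), on 3R from 8315899 to 8317980 (4.75) and on U from 4924832 to 4927021 (4.21). Their scores often repeated that of another region exactly (72.2%, against 0.444% of the other regions above 2, Fisher's exact test, p = 5.5e-55), as did 3 of the 6 regions above 2 in replicate 1 that replicate 2 lacked (p = 3.4e-05) and 4 of the 10 in replicate 2 that replicate 1 lacked (p = 2.0e-06). Exact repeats are what ratios of small numbers could give, so few counted reads behind the score may account for part of the pattern. The 54 were also narrow, with a median width of 1046.5 bp against 3788 bp for the other regions above 2. No enriched region of either replicate was narrower than 1301 bp, so most of the 54 were narrower than any replicate region. Their absence from the replicate lists therefore does not show that the signal was missing there. Of the 54, 53.7% lay off the major arms against 3.47% of the others (Fisher's exact test, p = 1.1e-24), as reads shared between copies of repeated sequence could give. Repeated sequence was not measured, so that explanation stays open on and off the major arms. The region on 2L from 21490625 to 21492636 (2.01), among the 54, lay at 21.4 to 21.56 Mb. So did the unshared regions starting at 21424016 and 21453405 in replicate 1 and at 21429922 in replicate 2. That stretch holds the evenly spaced row described below, but all of these regions lay outside the row itself.

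On 2L a row of regions was evenly spaced. From 21458293 to 21480653 in replicate 1, 5 regions started 5041 to 5060 bp apart, and the same row was in replicate 2 (5035 to 5058 bp) and in the series list (5040 to 5057 bp). It was the 1 run of at least 4 spacings equal within 100 bp in each list, and shuffled spacings gave as many with a one-sided p of at most 0.003. A unit of sequence repeated in tandem is a candidate explanation. The tandem array of histone genes is a candidate source: the release 6 gene table places all 111 replication-dependent histone genes of the list set beforehand on 2L, 87 of them with another as the next gene. Without an annotation of release 5 this stays untested, and how reads were shared among copies is not known.

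The YHet scaffold, named for the Y chromosome, held 5 enriched regions in each replicate and 8 in the series list, in cells labelled female, with scores from 1.39 to 3.15 in replicate 1 and from 1.29 to 2.27 in replicate 2. In each replicate 1 of the 5 was not found in the other. The score repeated that of another region exactly in 3 of the 5 in replicate 1, 1 of the 5 in replicate 2 and 3 of the 8 in the series list. On the major arms this held for 3.71%, 3.06% and 2.91% of the regions, in the same order. The shares were 18.5%, 17.5% and 31.9% on U, and 7.48%, 8.49% and 8.45% on the other heterochromatin scaffolds. Exact repeats were thus not particular to YHet, and no test was made on so few regions.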
